A study of Mus musculus with 2 samples.

How the data were processed

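RNA of 2 sorted T cell populations from mouse lymph nodes was measured on Illumina bead arrays, 1 array for conventional CD4 T cells and 1 for type 1 invariant NKT cells. Groups were taken from the cell type given in the sample labels. Per the labels' protocols, RNA was extracted with a QIAGEN RNeasy kit, and biotin-labelled cRNA was made from total RNA with the Illumina TotalPrep kit. The arrays were read with GenomeStudio 2009.2, per the submitters' processing notes. How the values were then normalised and filtered is not given in the sources used here.

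The authors deposited a non-normalized table with an intensity per probe and a value table. Per the file headers, each intensity column of the non-normalized table is followed by a detection p-value. Its 25697 probes had median intensities of 193 and 197, so signals of undetected probes, with medians of 166 and 168, had not been subtracted. Another 2 lines held annotation text and no probe, and were left out. In the first column 9456 probes (36.8%) had a detection p under 0.01, and in the second 9158 (35.6%). The deposited value table held log2 values of 11866 of these probes for the 2 samples, from 6.89 to 16.07. After sorting, its columns were equal within 0.00025 and had the same median of 9.07, as quantile normalisation leaves them, and no background had been subtracted. At least 1 of the 2 values lay at or above the level of a detection p of 0.05 for 11756 probes of the value table, and both lay below it for 110. Columns that could not be mapped to a sample numbered 0.

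The 2 deposited tables disagree for 1 sample. The value table of conventional CD4 T cells followed the first non-normalized column in rank (Spearman's rho 1). The value table of invariant NKT cells followed the second column with a rho of only 0.822, and the first with 0.823. The 2 non-normalized columns were nearly equal (Pearson's r 0.998 on the log2 scale, SD of the log2 ratio 0.0999, 0 probes 2-fold apart). All these are correlations across probes, which are not independent replicates. The plan fixed before the data were examined took the non-normalized signals as the main values, with background correction and quantile normalisation by neqc of limma 3.58.1 in R 4.3.3 at an offset of 16. That plan was departed from after the conflict was seen. The value table, whose columns are named by sample, became the main source, and the planned processing is an alternative, with effects given in the closing section. The second non-normalized column lacked the marker pattern of invariant NKT cells, with values given in the section on flagged results. That argues against it as the signals of that sample. Whether the value table holds the true signals of the invariant NKT sample stays unknown.

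Detection p-values were given only in the non-normalized table, so the detection level was the lowest value-table signal with a p under 0.01 in the first column, 7.83 on the log2 scale. Since the value columns share 1 distribution, that level was applied to the library labelled invariant NKT too, where it is an estimate. Probe names came from the platform annotation. Of the value-table probes, 11155 had 1 gene symbol, 0 had several and 711 had none. Gene identifiers of 11149 probes were found in the mouse RefSeq table for GRCm38.p6, and 0 symbols needed an update. No genome build was named for the probes, so no coordinates are given.

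For a gene with several probes, the probe with the highest mean log2 signal stood for the gene. With 1 array per group there were no residual degrees of freedom, so no p-value between the groups was computed and genes were called by size, at 2-fold or more. For a gene whose probes all lay below the detection level in 1 library, the bound is the bright library's value minus the higher of the detection level and the dim probe's own value. The SD of the log2 difference between 2 probes of a gene was the only measure of error, and it does not cover variation between animals, sorts or arrays. Folds are understated for dim genes, because background remained in the values.

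The 37 gene lists were fixed before the data were examined. A list's median covers members detected in 1 or both libraries, and it was set against 10000 random lists of the same size drawn from 20 bins of mean expression. After the data were seen, hepatocyte and neutrophil genes were also set against random lists drawn from the 1419 genes undetected in the library labelled conventional CD4 T, by their excess over the detection level. Lists with under 5 detected members got single values only. Genes were named by a rule fixed in advance, which took 188 genes. It took the 15 highest and 15 lowest genes detected in both libraries, the 10 largest bounds in each direction, up to 5 members of each list with the largest size, and 19 genes whatever their values. Of these the text names a part, some of the genes chosen in advance are not reported here, and genes chosen after their values were seen are said to be so. Genes of near-identical families (Klra, Ly6, Gzm, Hba, H2, clustered histones and Serpina1) are open to cross-hybridisation.

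The calling and list steps were tested on simulated data, a copy of the library labelled conventional CD4 T with noise of SD 0.25 on each array and 200 of 8116 genes changed. Of the 100 genes changed by 1.5 on the log2 scale, 77 were called, and of the 100 changed by 3, 99 were. Among 6162 unchanged genes, 28 were called. The simulated noise was smaller than the within-gene SD of the log2 difference in the data, 0.588, so that count is likely too low for these data. Changed genes were drawn only from genes well above the detection level, so recovery of dim genes was not tested. Of 100 lists of unchanged genes 2 passed the limits, and all 20 lists with changed members did. Alternatives covered the detection level, the filter, the probe rule, the fold threshold, the list members and 5 treatments of the non-normalized signals. Background subtraction from the value table, removal of an intensity trend and removal of genes with disagreeing probes were added after the data were seen. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.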

Results

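Gene expression was compared between 2 T cell populations of mouse lymph nodes, invariant natural killer T (NKT) cells and conventional CD4 T cells. Invariant NKT cells carry a T cell receptor of restricted diversity that recognises lipids presented by CD1d, whereas conventional CD4 T cells recognise peptides on MHC class II. The cells had been sorted with magnetic beads or by fluorescence, and total RNA of each population was hybridised to an Illumina mouse bead array. The design asked which transcripts differ between the populations. Each group held 1 array, so no value below has a replicate, no test between the groups was possible, and differences are described by their size on these 2 arrays. The deposited value table held quantile-normalised log2 signals of 11866 probes, 9447 of which reached the detection level in each library. That number is equal by construction, because both columns share 1 distribution and 1 level was applied to both. The named probes covered 8116 genes, of which 5989 were detected in both libraries. All differences are log2 signal in the library labelled invariant NKT minus log2 signal in the library labelled conventional CD4 T. For genes detected in 1 library only, a lower bound on the fold is given against the detection level of 7.83.

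The library labelled invariant NKT was far brighter for most detected effector cytokines, NK cell receptors and invariant NKT transcription factors, and far dimmer for most genes of naive T cells. Ifng, which encodes interferon gamma, was 108-fold higher (log2 difference 6.76), and its second probe was 32.0-fold higher. Il4, the cytokine of type 2 responses, was detected only in the library labelled invariant NKT, at least 38.3-fold above the detection level. Tbx21, the transcription factor that drives interferon gamma production, was higher by 3.37. Ccr7, the receptor that guides naive T cells into lymph nodes, was at least 22.6-fold lower, and Igfbp4, another transcript of naive T cells, differed by -5.53. The T cell identity gene Cd3e was near equal in both libraries, with a difference of 0.11.

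Among the genes detected in both libraries, 536 were 2-fold or more higher and 639 were 2-fold or more lower in the library labelled invariant NKT. Differences of 8-fold or more were held by 37 higher and 15 lower genes. A bound of 2-fold or more was reached by 137 of the 581 genes detected only in the library labelled invariant NKT and by 102 of the 674 detected only in the other. The within-gene SD of the log2 difference, from the 2 brightest probes of 1436 genes, was 0.588, and in 287 of these genes the 2 probes differed by more than 1 in their log2 difference. Of the 277 genes called at the brightest probe, 105 were called in the same direction at the second probe. These counts rest on the authors' value table. In the non-normalized table no probe differed 2-fold between its 2 columns. Every count of genes that differ 2-fold therefore became 0 with that table, which is no independent check of the value table.

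**Figure D1:**
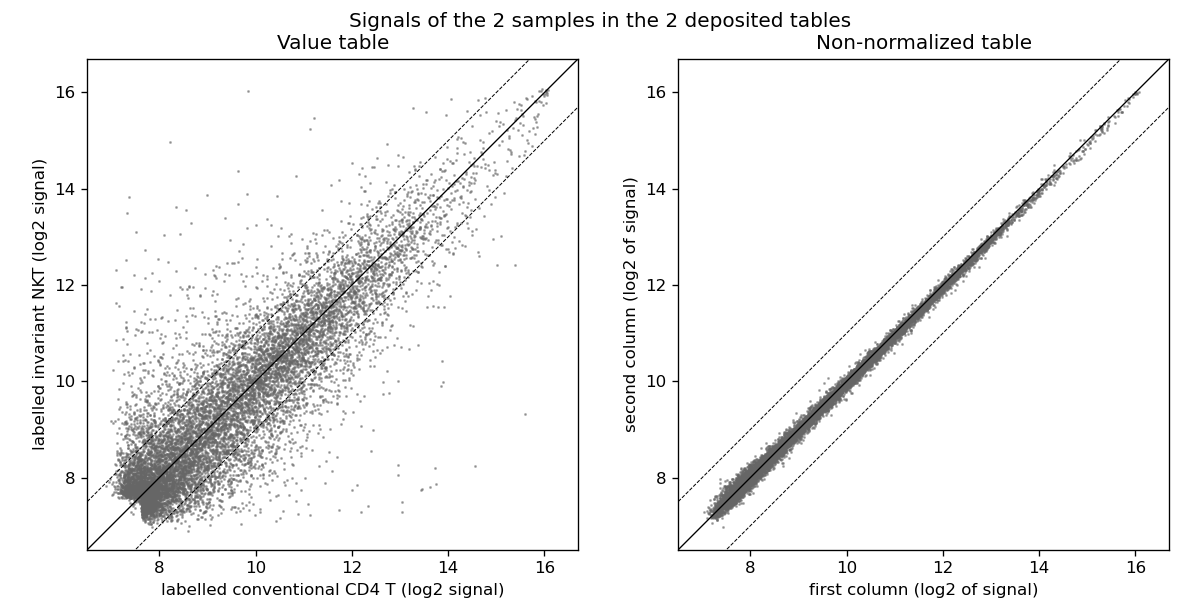
Log2 signal of each value-table probe in the 2 samples, in the value table on the left and in the non-normalized table on the right, with the line of equality and dashed lines at 2-fold. On the left 2266 probes differ 2-fold or more, and on the right 0 do.

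The labels were checked against marker genes. Cd4 itself differed by -0.61, from a log2 signal of 9.61 in the library labelled conventional CD4 T. Cd8b1, which encodes the beta chain of the CD8 co-receptor of cytotoxic T cells, had a log2 signal of 15.60 in the library labelled conventional CD4 T and 9.33 in the other, a difference of -6.27, and its second probe differed by -5.53. Itgae, which encodes the integrin CD103, was at least 49.0-fold lower in the library labelled invariant NKT, with all 6 probes lower. The fixed list of CD8 T cell markers had a median difference of -1.70, or -0.75 with genes of 1 library at their bound. Of its 5 detected members, 2 were 2-fold or more lower and 0 higher. It lay at percentile 0 of the matched random lists, 1 of only 3 lists in their bottom 2.5%. Both samples were labelled as female. The Y-linked genes Eif2s3y, Kdm5d and Uty, chosen after their values were seen, were nonetheless detected in the library labelled conventional CD4 T, at 11.55, 9.46 and 8.35. In the library labelled invariant NKT, Eif2s3y was detected too, with a difference of -2.55, while Kdm5d and Uty lay below the detection level. Because Cd8b1 and the Y-linked genes go against the labels, each group is called the library labelled so throughout, and every direction below depends on those labels.

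**Figure D2:**
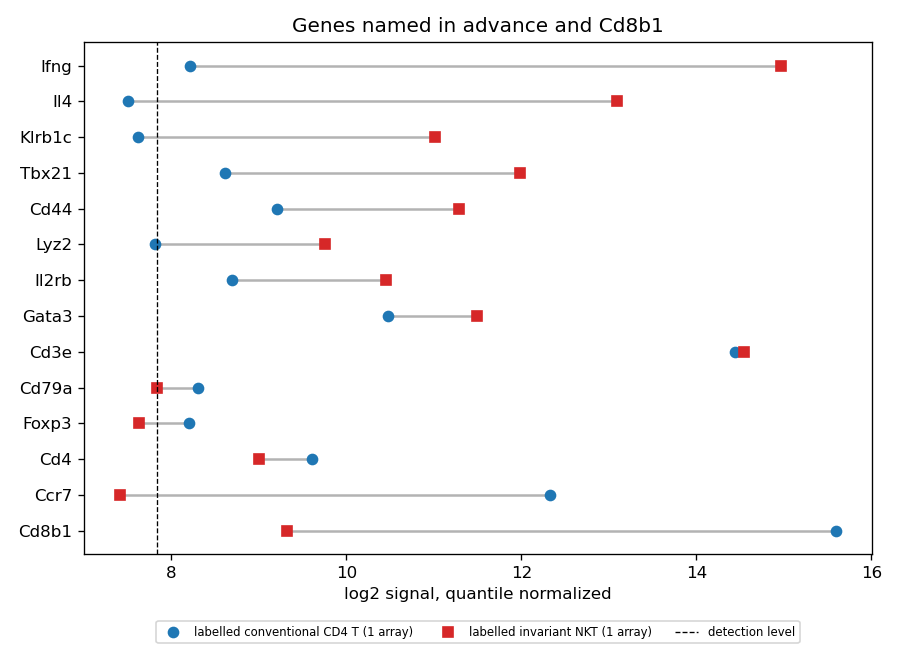
Log2 signal of the genes chosen before the data were examined and of Cd8b1, 1 array per group; circles show the library labelled conventional CD4 T, squares the library labelled invariant NKT, and the dashed line the detection level of 7.83. Ifng, Il4, Klrb1c and Tbx21 are brighter in the library labelled invariant NKT, and Ccr7 and Cd8b1 are brighter in the other.

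Gene lists fixed before the data were examined were then described by their median difference and its percentile among 10000 random lists matched on mean expression. Of the 34 lists with 5 or more detected members, 11 lay in the top 2.5% of random lists and 3 in the bottom 2.5%, where 1.7 in all would lie by chance. Lists share genes, and a member detected in 1 library only can differ in just 1 direction, so that excess is overstated. Over members detected in both libraries 8 lists lay higher and 3 lower, and without members of several lists 8 and 2. Invariant NKT transcription factors had the highest median, 2.93 (percentile 100), with 6 of 7 members 2-fold or more higher. With background subtracted their median was 3.48, below those of NKT1-type genes (3.94) and NK cell receptors (3.92), both described below. Bhlhe40 was higher by 3.23 and Rora by 3.08, and Gata3, the regulator of Il4, was higher by 1.02. Egr2, which is induced by T cell receptor signals, was the exception at -1.63. In the NKT1-type list, which holds genes of interferon-producing NKT cells, 12 of 13 members were 2-fold or more higher, with a median of 2.88 (percentile 100). Its members included Xcl1, a chemokine for dendritic cells (4.88), Cxcr3, a receptor for inflammatory chemokines (3.12), and Il2rb, the receptor chain shared by IL-2 and IL-15 (1.76).

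NK cell receptors had a median of 2.46 (percentile 100), and 8 of 12 were 2-fold or more higher. The median was 2.06 with genes of 1 library at their bound and 3.92 with background subtracted. Klre1 was higher by 4.58 and Cd160 by 4.07, while Klrb1c, which encodes the NK1.1 antigen, was at least 9.07-fold higher. Effector cytokines and chemokines had a median of 1.93 (percentile 100), with 10 of 12 members 2-fold or more higher, among them Tnf at 2.83 and Csf2 at a bound of 4.02-fold. NKT2-type genes had a median of 0.75 (percentile 99.5), and 4 of 9 were 2-fold or more higher, led by Il4. The probes of Icos, another member, went opposite ways, at 1.06 and -1.25. The NKT17-type list had a median of 0.04 (percentile 62.5), with Tmem176b higher by 1.89 and Aqp3 at -1.33. With members of several lists left out, its median was 1.16 (percentile 99.3). Cytotoxic granule genes had a median of 0.10 (percentile 71.0), although Fasl, which encodes a death ligand, was higher by 2.88 and Nkg7 by 1.58.

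Naive T cell genes had the lowest median, -2.59 (percentile 0), with 12 of 16 detected members 2-fold or more lower. It was -2.31 with genes of 1 library at their bound, and -1.51 over the 8 members detected in both libraries. With background subtracted it was -3.77, and the median of CD8 T cell markers lay lower, at -3.81. Besides Ccr7, Actn1 and Nsg2 were at least 55.0-fold and 37.1-fold lower, and Tdrp at least 18.0-fold. Ly6c1, named after its value was seen, was the 1 member 2-fold or more higher, at 1.15. The list of lipid antigen presentation and lysosome genes had a median of -0.75 (percentile 0.35), with 4 of 11 members 2-fold or more lower, such as Npc2, a carrier of cholesterol in lysosomes, at -2.05. Cd1d1, which encodes the lipid-presenting molecule itself, went the other way and was at least 4.59-fold higher in the library labelled invariant NKT. Cytokine receptors had a median of 0.33 (percentile 95.8). The list lay among the highest random lists with background subtracted (median 0.57, percentile 98.7) and without genes whose probes disagree (0.64, 99.7). Its members split both ways: Il12rb1 was at least 9.07-fold higher, and Il6st, the signal chain of the IL-6 receptor, was at least 7.20-fold lower.

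Activation and memory genes had a median of 0.61 (percentile 99.9), with 8 of 18 members 2-fold or more higher and 3 lower. The median was 0.26 with genes of 1 library at their bound, and 0.22, no longer apart from random lists (percentile 92.9), at a detection p under 0.05. Cd44, a marker of antigen-experienced T cells, was higher by 2.08, S100a6 by 2.89 and Tnfrsf18 by 2.56, whereas the inhibitory receptor Ctla4 differed by -2.44. Immediate early and sort stress genes had a median of 0.87 (percentile 100), and 10 of 23 were 2-fold or more higher. Hspa1a, an inducible heat shock protein, was at least 64.0-fold higher, and Gadd45b and Nfkbia were higher by 4.63 and 3.44. Cell cycle genes had a median of 0.64 (percentile 99.97), with 5 of 20 members 2-fold or more higher, Hmgb2 at 2.61 and Birc5 at 1.64 among them; the median was 0.52 at the bounds and 1.24 with background subtracted. The SLAM family and SAP pathway, which NKT cells need to develop, had a median of 0.58 (percentile 98.4), with Ly9 at 1.25 and Slamf1 at 1.13. It no longer stood apart with background subtracted (percentile 95.5) or over members detected in both libraries (96.2), nor did the NKT2-type list over the latter (96.9).

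**Figure D3:**
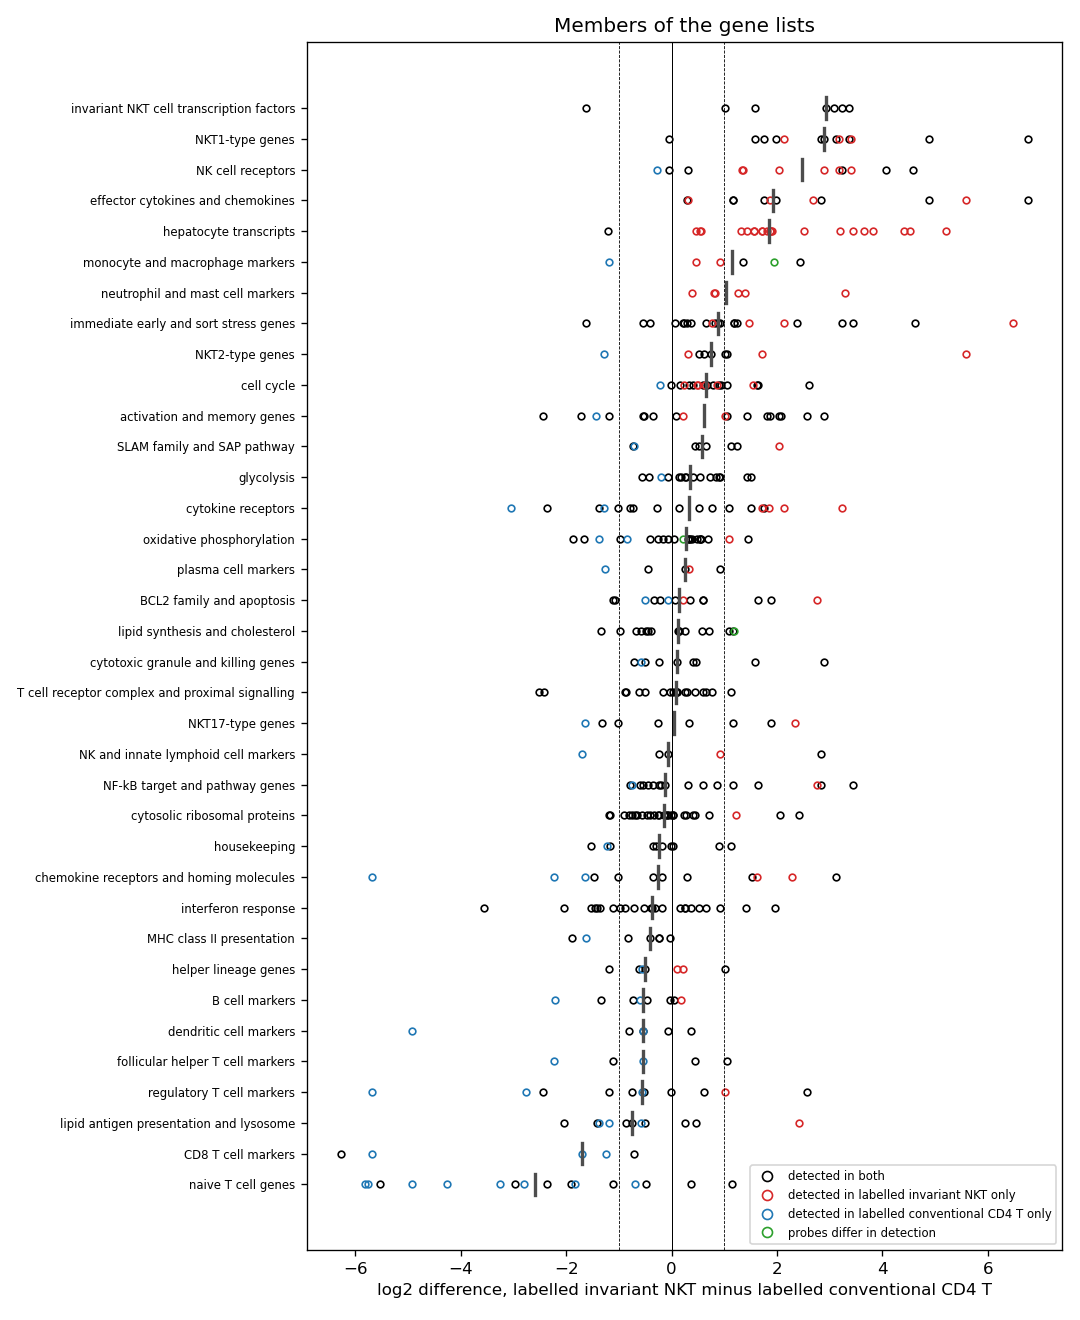
Log2 difference, library labelled invariant NKT minus library labelled conventional CD4 T, of each member of each list with 5 or more detected members; vertical bars are list medians and dashed lines mark 2-fold. Hepatocyte transcripts and helper lineage genes were listed after the data were seen. Medians run from 2.93 for invariant NKT transcription factors to -2.59 for naive T cell genes.

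Some markers of other cell types were shifted as well. Monocyte and macrophage markers had a median of 1.14 (percentile 99.9) over 6 detected members, of which 3 were 2-fold or more higher and 1 lower. The median was 0.90 with genes of 1 library at their bound, 0.72 at a detection p under 0.05 and 2.00 with background subtracted. Cebpb was higher by 2.43, Ctss was at least 2.20-fold lower, and the 2 probes of Lyz2, the lysozyme gene of myeloid cells, differed by 1.94 and -0.52. Neutrophil and mast cell markers had a median of 1.04 (percentile 99.97) over 6 members, which became 0.43 at their bounds and 3.18 with background subtracted, and S100a8 was at least 5.99-fold higher. All 6 were undetected in the library labelled conventional CD4 T, and against random lists of genes undetected there the 7 members on the table lay at percentile 94.0. Among red cell genes, Hba-a1, which encodes alpha globin, was higher by 6.20, and Alas2 and Slc4a1 were at least 25.7-fold and 6.01-fold higher. Hepatocyte transcripts, a list drawn up after the data were seen, had a median of 1.84 over 22 members. It was 1.30 with genes of 1 library at their bound and 4.57 with background subtracted. Of the 22 members, 16 were 2-fold or more higher. Among these, Serpina1b and Serpina1d, near-identical liver antitrypsin genes whose probes are open to cross-hybridisation, were at least 22.2-fold and 13.9-fold higher. The other 13 listed genes had no named probe on the value table. Compared only with genes undetected in the library labelled conventional CD4 T, 14 such members other than those that had drawn attention exceeded the detection level by a median of 1.24 (percentile 100). B cell markers did not stand apart, with a median of -0.54 (percentile 4.60, and -0.33 at the bounds) and Cd79a at -0.46, and MHC class II genes did not either, at -0.42 (percentile 16.2). Nor did regulatory T cell markers, at -0.57 (percentile 3.54), with Foxp3 below the detection level in the library labelled invariant NKT. That list lay among the lowest random lists under 4 other settings: at a detection p under 0.05 (percentile 1.68), without a detection filter (1.54), with the mean of a gene's probes (2.27) and with background subtracted (0.32, at a median of -1.57).

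Several programmes did not stand apart from random lists. The T cell receptor complex had a median of 0.09 (percentile 76.9), although Lat and Ptprc were lower at -2.51 and -2.42. Interferon response genes had a median of -0.38 (percentile 3.20), with 7 of 24 members 2-fold or more lower, such as Oasl2 at -3.56, and 2 higher, Isg15 at 1.97 and Psmb8, named after its value was seen, at 1.41. Medians were 0.34 for glycolysis (percentile 95.5), 0.26 for oxidative phosphorylation (95.1), 0.14 for BCL2 family genes (80.8) and 0.12 for lipid synthesis (80.9). Over members detected in both libraries, glycolysis lay among the highest random lists (median 0.41, percentile 97.6) and interferon response among the lowest (2.11). Medians were -0.13 for NF-kB genes (percentile 40.8), -0.14 for cytosolic ribosomal proteins (23.4), -0.24 for housekeeping genes (19.8) and -0.27 for chemokine receptors and homing molecules (20.03). With members of several lists left out, the last became 0.91 and lay among the highest random lists (percentile 98.9). Of the 10 housekeeping genes, 1 was 2-fold or more higher, Actb at 1.12, and 2 were lower, Ywhaz at -1.53 and Rplp0 at -1.17. Dendritic cell markers measured -0.54 (percentile 9.26, and -0.30 at the bounds), follicular helper markers -0.55 (10.9, and -0.14), plasma cell markers 0.25 (73.6, and 0.04 at the bounds) and NK and innate lymphoid markers -0.06 (49.2). Too few members were detected to place the red cell and platelet, gamma delta T cell and stroma lists, in which Cd163l1 measured -0.26 and Pecam1 -2.23.

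Single genes outside the lists reached similar sizes. Socs2, a feedback inhibitor of cytokine signalling, was at least 51.0-fold higher in the library labelled invariant NKT, and the related Cish was higher by 4.03. Asb2, a ubiquitin ligase subunit, differed by 5.29, Lrrk1 by 4.95, Rpl24 by 4.74 and Aqp9 by 4.64, and Mmp9 was at least 29.7-fold higher. Rpl24, a ribosomal protein gene, had 1 probe, and the list of cytosolic ribosomal proteins did not rise with it (median -0.14). In the other direction Amigo2 differed by -4.27, St6gal1, a sialyltransferase, by -3.95, Rgs10 by -3.90, Trib2 by -3.85 and Gpr183, an oxysterol receptor, by -3.02. Pdlim4 was at least 20.5-fold lower. Zbtb16, Cd8a and Il17a were also chosen in advance and were not analysed here.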

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

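The tests of normalisation, of the 2 non-normalized columns, of the Cd8b1 probes, of the Y-linked genes and of the hepatocyte genes were chosen after the results were seen. The helper genes were listed after the data were first examined, but before their values were. Among probes without a gene symbol, which the comparisons above do not use, 53 were 2-fold or more higher in the library labelled invariant NKT, and 81 were 2-fold or more lower. Their genes were not analysed here.

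The 2 deposited tables gave different values for the sample labelled invariant NKT. Normalisation or filtering of the same array would keep the order of probes, and the rank correlation was 0.822 across probes, which argues against it. Probes put out of order throughout the invariant NKT column of the value table would leave it unrelated to the other column. The rank correlation of the 2 value columns was 0.823 across probes, which argues against that. The log2 differences of 2 probes of a gene correlated at 0.539 across 1436 genes. That value cannot decide the question, because both differences also hold the signals of the other library. Between the non-normalized columns, 0 probes differed 2-fold, so the second column may be a further array of RNA like that of the first. A column of invariant NKT cells would differ from conventional CD4 T cells in NKT1-type and naive T cell genes. With the planned processing of the non-normalized signals, the medians were 0.02 over 10 NKT1-type and 0.03 over 16 naive T cell genes. In the value table they were 2.88 over 13 and -2.59 over 16. That argues against the second column as signals of invariant NKT cells, if the first is of conventional CD4 T cells. The second column's own signals do not rest on that condition. There Il4 and Klrb1c had detection p-values of 0.038 and 0.055. Ifng and Tbx21 were detected but dim, at 322 and 408, against 5439 for Ccr7 and 38228 for Cd8b1. Whether the submitters placed the wrong column there was not tested.

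Cd8b1 and Y-linked genes were bright in the library labelled conventional CD4 T. A single cross-hybridising probe would not explain Cd8b1, since its second probe also differed by -5.53. If CD8 T cells made up part of that library, the helper genes Zbtb7b, Cd40lg, Tnfrsf4 and Cd5 would not be brighter there by 1 or more. Their median difference was -0.20, but 2 of the 4 lay near the detection level. That difference also depends on the helper genes of the library labelled invariant NKT, so it cannot separate CD4 from CD8 T cells in the other. Of Eomes, Crtam, Gzmm and Itgae (median -0.73 at their bounds) only 1 was detected in both libraries. Within the library labelled conventional CD4 T alone, Cd8b1 lay at percentile 99.7 of probes and Cd4, on 1 probe, at 59.1. Itgae lay at 97.2, and Gzmm, Eomes and Crtam at 53.0, 40.8 and 38.1. So bright a Cd8b1 signal, with its second probe in the same direction, argues against CD4 T cells alone in that library. The share of CD8 T cells there, which sorting for CD4 should remove, stays open. All 3 measured Y-linked genes were detected there, and Eif2s3y in the other library too, as RNA of male animals would give. Their gap to the X-linked copies, a median of -1.23 over 2 pairs, argues against signal of those copies alone. The gap of Uty is inexact, because Uty lay below the detection level in the library labelled invariant NKT (bound -0.51). A wrong sample or a mixed sort could give either sign, and the difference between cell types that the design names stays open for Itgae, Eomes, Crtam and Gzmm.

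Hepatocyte and red cell transcripts were brighter in the library labelled invariant NKT. Against other genes undetected in the library labelled conventional CD4 T, 14 hepatocyte genes other than those that drew attention exceeded the detection level by a median of 1.24, at percentile 100 of random lists, as RNA of hepatocytes would give. Such RNA would bring all abundant liver transcripts, however, and 13 of the 35 listed genes had no named probe on the value table, where 11756 of 11866 probes reached the level of a detection p of 0.05 in 1 or both libraries. Whether these 13 were filtered out as dim or had no probe was not tested, so hepatocyte RNA stays open. Apoa2, Trf and Apoc1 were at least 8.28-fold, 7.67-fold and 6.03-fold higher, and of the whole list only Ass1, at -1.21, was detected in the library labelled conventional CD4 T. Apoe is also a macrophage marker in the fixed lists, and a T cell sort should remove hepatocytes. For red cells, the other 2 list members had a median of 1.55, with Slc4a1 raised and Itga2b, a platelet gene, detected in neither library, so red cell RNA could not be judged from so few genes.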

How the results depend on the processing

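Settings on background subtraction, intensity trend and disagreeing probes were added after the data were seen. No paired analysis was possible because each group held 1 sample and no replicate numbers were given; likewise no library could be left out. With each of the 5 treatments of the non-normalized signals, the counts of higher genes, of lower genes, of genes bounded in either library, of shifted lists in either direction and of named genes at 2-fold were all 0. Over these treatments the largest difference of a named gene was 0.86, and list medians lay from -0.16 to 0.06. Of 188 named genes, 81 to 84 had the other sign. The 2 non-normalized columns were nearly equal before any treatment, so these values follow from that and do not test the results of the value table. On the value table, a 1.5-fold threshold gave 1090 higher and 1346 lower genes, and a 3-fold threshold 195 and 196, as their construction implies. Subtracting the background raised the bounded genes from 137 to 286 in the library labelled invariant NKT and from 102 to 300 in the other. Taking the same background from signals and detection level widens bounds above that level, so the rise follows from the step. The lists shifted lower rose from 3 to 5, and the cause of that was not tested. Other counts stayed within 1.5 times, from 484 to 785 higher and from 564 to 955 lower genes. Of 253 list medians under other settings of the value table, 213 moved by less than the standard error that the within-gene probe SD gives a median of as many genes, 40 moved more and 0 of the shifted lists turned; the limits set by random lists were passed or missed as before in 237 cases, newly missed in 5 and newly passed in 11. With background subtracted, the CD8 median became -3.81 and that of activation genes 0.98. Of 744 values of named genes under such settings, 633 moved by less than the probe SD, 110 moved more, 96 of them with background subtraction, and 1 turned: Icos was -0.095 as the mean of its probes, which differed in sign. With members of several lists left out, 8 lists lay higher and 2 lower. The 8 included the NKT17-type list (median 1.16, percentile 99.3) and chemokine receptors (0.91, 98.9), neither of which had stood apart before. Interferon genes lay among the lowest lists with background subtracted (percentile 1.33), and cytokine receptors among the highest (98.7, and 99.7 without genes whose probes disagree). Signal over background limits dim genes: 838 genes reached the detection level in neither library.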

Other observations

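Families in this part and their tests were chosen after the values were seen, so their medians are no test of a shift, and the helper lineage list was drawn up after the data were first examined. Genes of the clustered histones had a median difference of 0.79 over 34 detected members, with 14 of them 2-fold or more higher in the library labelled invariant NKT and 1 lower. H2ac7 was higher by 4.09, H2ac15 by 3.35 and H2ac12 by 3.25, and H2bc18 differed by -1.35. Their sequences are near-identical, so probes are open to cross-hybridisation and members are not independent. Cyclin-dependent kinase inhibitors were higher in the same library as the cell cycle list: 4 of 5 were 2-fold or more higher, with Cdkn1c at 2.00, Cdkn2c at 1.51 and Cdkn1b at 1.09. All 3 stress-induced Gadd45 genes were higher, Gadd45g by 2.33 and Gadd45a by 2.04. Histone medians lay from 0.68 to 1.36 over the other settings of the value table, and from -0.08 to 0.02 with the non-normalized signals.

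Zinc finger genes named Zfp had a median of -0.30 over 144 members. Of these 14 (9.72%) were 2-fold or more lower and 2 (1.39%) higher, against 10.25% and 9.37% of all genes detected in 1 or both libraries, so few were higher and no more than usual were lower. That median lay from -0.50 to -0.27 over the other settings of the value table, and from -0.09 to 0.00 with the non-normalized signals. Of 16 genes named Gpr, 6 were 2-fold or more lower and 0 higher, Gpr183 and Gpr18 among them at -3.02 and -2.12, and the family median was -0.17. Helper lineage genes had a median of -0.51 (percentile 5.38) over 7 members.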
